A study of Mus musculus with 4 samples.

How the data were processed

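Total RNA of microglia isolated from the corpus callosum of mouse pups was sequenced on an Illumina instrument, per the labels. The 4 libraries fall into 2 groups of 2, floxed Lag3 mice with the genotype label wt (WT) and mice with Lag3 deleted in cells that use the Cx3cr1 driver, with the genotype label ko (cKO). Nothing in the labels says whether a library is 1 animal or a pool, so p-values measure only the spread between these libraries.

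The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.0 and the build mm9, without the settings, the strand or the annotation. The gene positions in the deposited table matched GRCm38 instead, since 92.1% of the 21008 genes shared with GENCODE M21 had the same chromosome, start and end, and positions are given here as GRCm38. The authors deposited FPKM values for 21044 genes, and 4 tables that each compare 1 cKO library with 1 WT library. Each of these tables holds read counts per gene, per the file headers, besides a normalized signal, which is the CPM with a count of 0 replaced by 0.5. The tables also hold the authors' fold change as a ratio, its log2 value, and a p-value and adjusted p-value, and the test behind them is not given in the sources used here.

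Counts were joined over the 4 tables for 18459 genes. The 2 tables that hold a given library had 0 genes with different counts. Where a gene was missing from both tables of a library, its count was recovered from the FPKM value, which differed from the count by 1 factor per gene and 1 per library. This filled 4315 of 73836 cells, of which 100.0% were whole within a tolerance of 1e-06, the highest being 4. The other 2585 genes of the FPKM table, with a highest FPKM of 7.42, had no counts and were left out of the count tests. Total counts ranged from 14645187 to 16770162 per library. The WT libraries differed from each other by more than sampling noise, with a chi-square of 27.8 per degree of freedom over genes, and the cKO libraries did so with 107.5, so each library was used as its own sample. Intervals were not computed for single counts, and the floor of 3 counts per library used for genes at 0 covers counting error only.

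The main comparison used edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr and the quasi-likelihood F test, at a Benjamini-Hochberg adjusted p under 0.05. CPM values given here are scaled by TMM. Standard errors of log2 fold changes were derived from the F statistic. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, adjusted over 28 lists together, and 3 quality lists were described without a call. The lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined. Named genes are Lag3 and Cx3cr1, then up to 10 genes per direction past the threshold, filled to 5 by the smallest unadjusted p among genes at a mean of at least 5 CPM whose groups did not overlap, then up to 4 members of each list with the smallest p. Predicted and clone-named genes, microRNA genes, pseudogenes and genes without a symbol were left out of the genes named per direction. A list member counted as expressed at a mean of at least 1 CPM, a value set after the data were examined. This gave 120 genes, and members named outside the rule are said to be so.

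The alternatives were DESeq2 1.42.0, other scaling factors, other filters on low counts, limma on log2(FPKM + 1) and with pseudocounts of 0.1 and 0.5, a replicate block, leaving out each library, camera with an estimated correlation, and fry. For the authors' tables, genes called in the same direction in 1 to 4 tables were counted, and the call rule of the tables, 2-fold or more at p under 0.05, was applied to 20 simulated sets of unchanged libraries with the fitted dispersions of 13086 genes, a check added after the data were examined. Applied to the real counts, this rule gave the call of the authors' deposited tables for at least 99.4% of genes in each table.

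The scripts were tested on simulated data for cKO against WT with 12049 genes, 200 of them changed. The edgeR test recovered 0% of genes changed 2-fold, 25.4% of those changed 4-fold and 77.3% of those changed 16-fold, with 10 unchanged genes called. DESeq2 recovered 8.96%, 58.2% and 95.5%, with 109 unchanged genes called. On the real counts edgeR called 0 genes and DESeq2 called 52 in all. The simulated rates of recovery and of false calls therefore do not carry over to the real libraries. A 33-gene list changed 4-fold was called by camera with the preset correlation, with 0 of 27 unchanged lists called. With an estimated correlation camera gave that list an adjusted p = 0.326. Genes were simulated independently of each other. The 0 of 27 therefore gives no rate of false calls for lists whose members move together between libraries. Of the named genes, 30 share exon sequence with another annotated gene, 23 of them on the opposite strand only. Their counts are uncertain, since the strand setting and the handling of reads in shared exons are not given. Counts of H2-K1, H2-D1, Ifi204 and other members of gene families are uncertain because reads can be shared with near-identical paralogs.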

Results

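Gene expression was measured by RNA-seq in microglia isolated from the corpus callosum of mouse pups at postnatal day 7. The libraries comprised 2 from floxed Lag3 mice (WT) and 2 from mice in which Lag3, an inhibitory immune receptor, was deleted through a Cx3cr1 driver (cKO). Total counts were 15855913 and 14973059 in the WT libraries and 16770162 and 14645187 in the cKO libraries. Genes with at least 1 count numbered 14840 and 15899 in WT replicates 1 and 2, 15491 in cKO replicate 1 and 12787 in cKO replicate 2. The second cKO library stood apart from the rest. Across genes, which are not independent replicates, its log2 CPM correlated with those of the other libraries at r = 0.783 to 0.802, against 0.872 to 0.91 among the other 3.

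The study asked what loss of LAG3 does to microglia of the early postnatal white matter. Lag3 (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705 on the minus strand, GRCm38) had 6064 and 10007 counts in the WT libraries and 595 and 257 in the cKO libraries. Its level was 534.9 ± 209.5 CPM (SD, n = 2) in WT and 26.28 ± 12.94 CPM (SD, n = 2) in cKO, a log2 fold change of -4.35 with a standard error of 0.52. Which exons the floxed allele removes is not given in the sources used here, and the counts cover the whole gene. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879 on the minus strand), the fractalkine receptor and the locus of the driver, was at 6498 ± 78.5 CPM (SD, n = 2) in WT and 3219 ± 262.2 CPM (SD, n = 2) in cKO, with a log2 fold change of -1.01 and a standard error of 0.13. Neither passed the edgeR test over all genes, and both passed DESeq2, with adjusted p = 1.46e-20 for Lag3 and 4.08e-05 for Cx3cr1. Cx3cr1 also passed edgeR when adjusted over the list alone, with adjusted p = 0.0209 among the 29 homeostatic genes. Both cKO libraries carry the driver as well as the deletion of Lag3. Differences from WT can therefore not be credited to the loss of Lag3 alone.

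**Figure D1:**
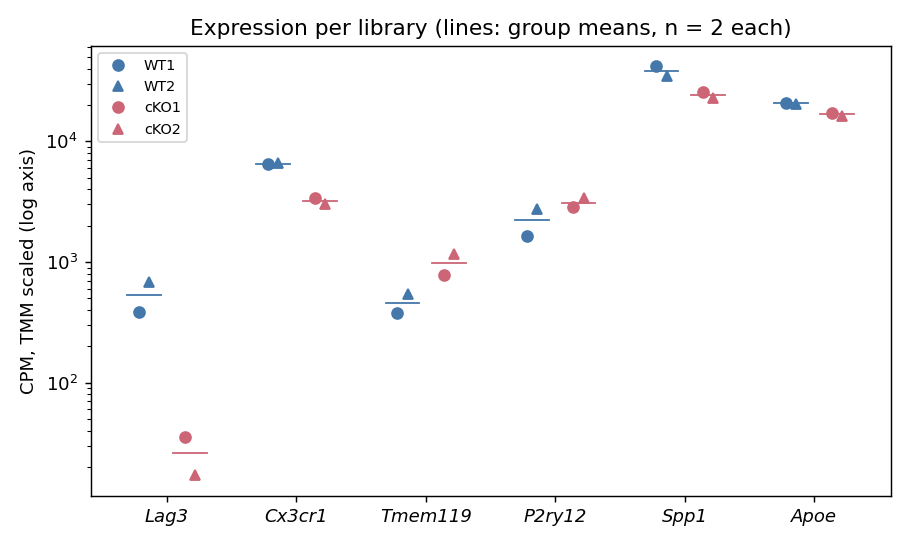
CPM on a log axis for 6 genes in each WT (blue) and cKO (red) library, with circles for replicate 1, triangles for replicate 2 and lines for the group means. Lag3 is at 386.7 and 683 CPM in WT and at 35.4 and 17.1 CPM in cKO, while Cx3cr1 lies at 6443 and 6554 CPM in WT and at 3404 and 3034 CPM in cKO.

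Beyond Lag3 and Cx3cr1, genes were taken by the smallest unadjusted p among those that the rule allows to be named. Those higher in both cKO libraries were Pxdc1, Ifi44, Iigp1, Klhl7 and Fcho2, and those lower were Kif3b, Tmem127 and Snx8. None of them passed the edgeR test, and Pxdc1, Ifi44, Iigp1, Kif3b, Tmem127 and Snx8 passed DESeq2, with adjusted p = 0.000272 to 0.0425. Klhl7 was at 76.3 ± 3.89 CPM (SD, n = 2) in WT and 161.2 ± 27.2 CPM (SD, n = 2) in cKO. Kif3b, a kinesin motor subunit, was at 69.6 ± 27.9 CPM (SD, n = 2) in WT and 14.6 ± 0.034 CPM (SD, n = 2) in cKO. Ifi44, an interferon-induced gene, had no count in either WT library and 11.6 ± 1.55 CPM (SD, n = 2) in cKO, at least 58.4-fold higher against a floor of 3 counts per library. Of 13086 genes tested with edgeR, 0 had an adjusted p under 0.05, the lowest adjusted p being 0.9997, and 608 had an unadjusted p under 0.05, against 654.3 given by no change. DESeq2 called 52 genes, 23 higher and 29 lower, of which 39 had fewer than 10 counts in a whole group. In the simulated data it called 109 unchanged genes, more than all its calls here. That number therefore gives no rate of false calls for these libraries. Without cKO replicate 1, edgeR called 748 genes, 106 higher and 642 lower, in a fit where the lone cKO library is assumed to vary like the WT libraries. At a mean of at least 5 CPM, both cKO values lay on one side of both WT values for 36.2% of 9426 genes, where chance gives 33.3%.

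Homeostatic microglial genes had a median log2 fold change of 0.18 over 29 genes, 20 of them fitted higher, and the list did not pass camera, with adjusted p = 0.152 (0.0493 without WT replicate 2). Its median ranged from 0.057 to 0.32 over leaving out each library. Tmem119, a marker of resident microglia, was at 460.9 ± 113.1 CPM (SD, n = 2) in WT and 972.8 ± 282.2 CPM (SD, n = 2) in cKO, and Lpcat2 and Selplg also lay above WT in both cKO libraries, with log2 fold changes of 0.91 and 0.99. Genes of disease- and axon-tract-associated microglia, the state of early white matter, had a median log2 fold change of -0.31 over 29 genes, and 17 of them were below both WT libraries in both cKO libraries, but the list did not pass camera, with adjusted p = 0.256, and its median was -0.16 without cKO replicate 2 and -0.49 without cKO replicate 1. Spp1, encoding osteopontin, was at 38320 ± 4799 CPM (SD, n = 2) in WT and 24250 ± 1750 CPM (SD, n = 2) in cKO, a log2 fold change of -0.66 with a standard error of 0.14, and the lysosomal protease Ctsd had a log2 fold change of -0.56. Axl and Cybb of the same list were higher, with log2 fold changes of 1.00 and 1.15. Itgax, Apoe and Igf1 had log2 fold changes of -1.05, -0.31 and -0.81, and the homeostatic receptor gene P2ry12 one of 0.49, all 4 chosen after their values were seen. Of the homeostatic genes, 10 lay above both WT libraries in both cKO libraries and 3 lay below. Sall1, among the latter and likewise chosen after its value was seen, had a log2 fold change of -0.485. None of these genes passed the edgeR test over all genes.

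Interferon response genes formed the list with the smallest p by camera with the preset correlation, but not with an estimated correlation or by fry. All 33 were fitted higher in cKO, 23 lay above both WT libraries in both cKO libraries, and the median log2 fold change was 1.73, with camera adjusted p = 3.21e-14 (adjusted p = 0.681 with an estimated correlation). No member passed edgeR over all genes, 0 passed when adjusted over the list alone, and 4 passed DESeq2. Ifih1, a sensor of viral RNA, was at 40.8 ± 15.2 CPM (SD, n = 2) in WT and 124.7 ± 16.2 CPM (SD, n = 2) in cKO, and Ifi27l2a and Trim30a had log2 fold changes of 3.32 and 1.13. The WT libraries differed in this list as much as the groups did. WT replicate 1 exceeded WT replicate 2 by a median of 1.74 on the log2 scale, cKO replicate 2 exceeded cKO replicate 1 by 1.31, and cKO replicate 1 exceeded WT replicate 1 by only 0.35. The median was 0.93 without cKO replicate 2, 1.12 without WT replicate 2 and 3.43 without WT replicate 1. In cKO replicate 2 over cKO replicate 1, markers of neutrophils and monocytes had a median of 1.81 and those of astrocytes 0.86. The median was below 0 for 5 of the 7 lists of other cell types with at least 5 members.

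**Figure D2:**
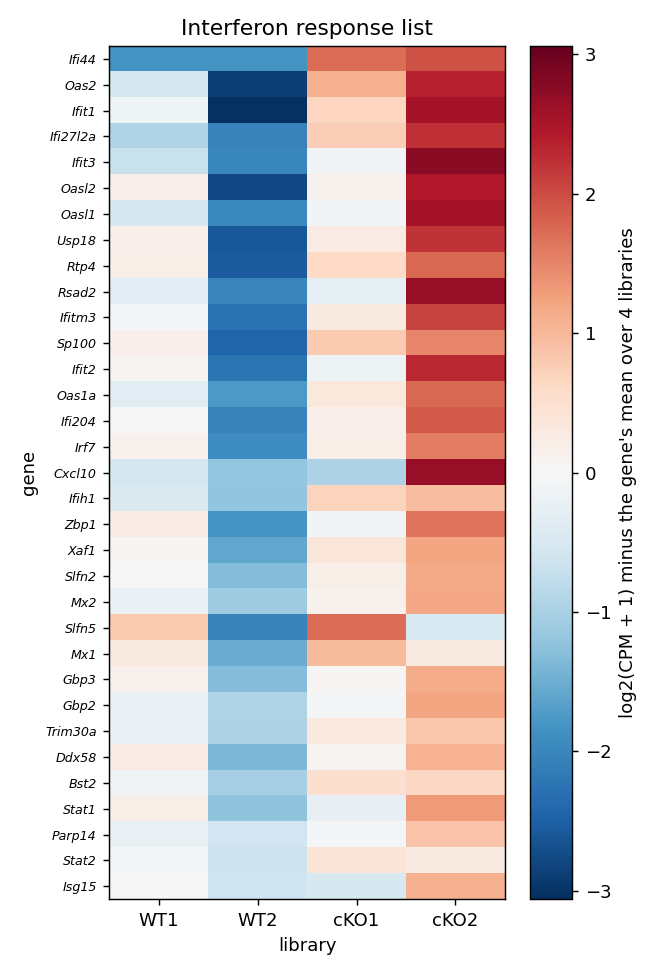
Heat map of the 33 interferon response genes (rows) in the 4 libraries (columns), as log2(CPM + 1) minus the mean of the gene over the libraries, with red above and blue below that mean. WT replicate 2 is lowest and cKO replicate 2 highest for most genes, and WT replicate 1 and cKO replicate 1 lie close together, 0.35 apart in the median on log2 CPM.

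Smaller differences in the same direction were found in genes of inflammation, antigen presentation and the cell cycle. Inflammatory cytokines and NF-kB targets had a median log2 fold change of 0.35 over 22 genes, with camera adjusted p = 0.000977 (adjusted p = 0.681 with an estimated correlation). The cytokine genes Tnf, Il1a and Il1b were above WT in both cKO libraries, with log2 fold changes of 1.75, 1.02 and 1.52. Antigen presentation genes had a median of 0.46 over 19 genes, with camera adjusted p = 0.00312 (adjusted p = 0.681 with an estimated correlation), and the MHC class I genes H2-D1, H2-K1 and B2m had log2 fold changes of 0.80, 0.75 and 0.54. Cell cycle genes had a median of 0.36 over 38 genes, with camera adjusted p = 0.000977 (adjusted p = 0.681 with an estimated correlation), and Hmgb2, Prc1 and Cenpe had log2 fold changes of 0.73, 0.99 and 1.07. None of the 9 genes named here passed the edgeR test over all genes. Without cKO replicate 2, antigen presentation and the cell cycle no longer passed camera, with medians of 0.27 and 0.19 and adjusted p = 0.0729 and 0.204, and the lists past the threshold numbered 3 rather than 6. The median of the inflammatory list was 0.57, 0.61, 0.69 and 0.28 without WT replicate 1, WT replicate 2, cKO replicate 1 and cKO replicate 2. In cKO replicate 2 over cKO replicate 1 it was 0.63, where the markers of neutrophils and monocytes, cells that also express cytokine genes, had a median of 1.81. The part of such cells in the cytokine counts was not tested.

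Markers of astrocytes were higher in cKO, and those of neutrophils and monocytes in cKO replicate 2. In cKO replicate 1 the latter had a median of -0.64 over WT replicate 1 and 0.56 over WT replicate 2. All 14 astrocyte markers were fitted higher in cKO, with a median log2 fold change of 1.42 and camera adjusted p = 4.17e-06 (adjusted p = 0.681 with an estimated correlation). The glutamate transporter gene Slc1a3 was at 39.4 ± 8.09 CPM (SD, n = 2) in WT and 106.8 ± 36.2 CPM (SD, n = 2) in cKO, and Sox9 had a log2 fold change of 2.42, neither passing edgeR. The median was 0.74 without cKO replicate 2. The counts of these markers were low, summing to 232.5 CPM in WT and 444.3 CPM in cKO on average. The sums were 255.2 and 209.8 CPM in the WT libraries, and 292.8 and 595.8 CPM in cKO replicates 1 and 2. Neutrophil and monocyte markers had a median of 1.28 over 8 genes, with camera adjusted p = 0.0087 (adjusted p = 0.762 with an estimated correlation). The difference rested on cKO replicate 2, without which the median was -0.04 and the adjusted p = 0.594. Without WT replicate 2 the median was 1.14, and the call was lost, with adjusted p = 0.169. Ngp of this list passed DESeq2, with adjusted p = 0.0093. The other 22 of the 28 lists did not pass camera. Y-linked transcripts differed inside the cKO group, where Ddx3y had 106.9 CPM in replicate 1 and 0 in replicate 2, against 94.7 and 89.1 CPM in WT. Xist was at 0 in both WT libraries, at 6.97 CPM in cKO replicate 1 and at 290.4 CPM in cKO replicate 2. The groups are thus not matched for these transcripts. Differences linked to sex cannot be fully told from those linked to genotype.

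**Figure D3:**
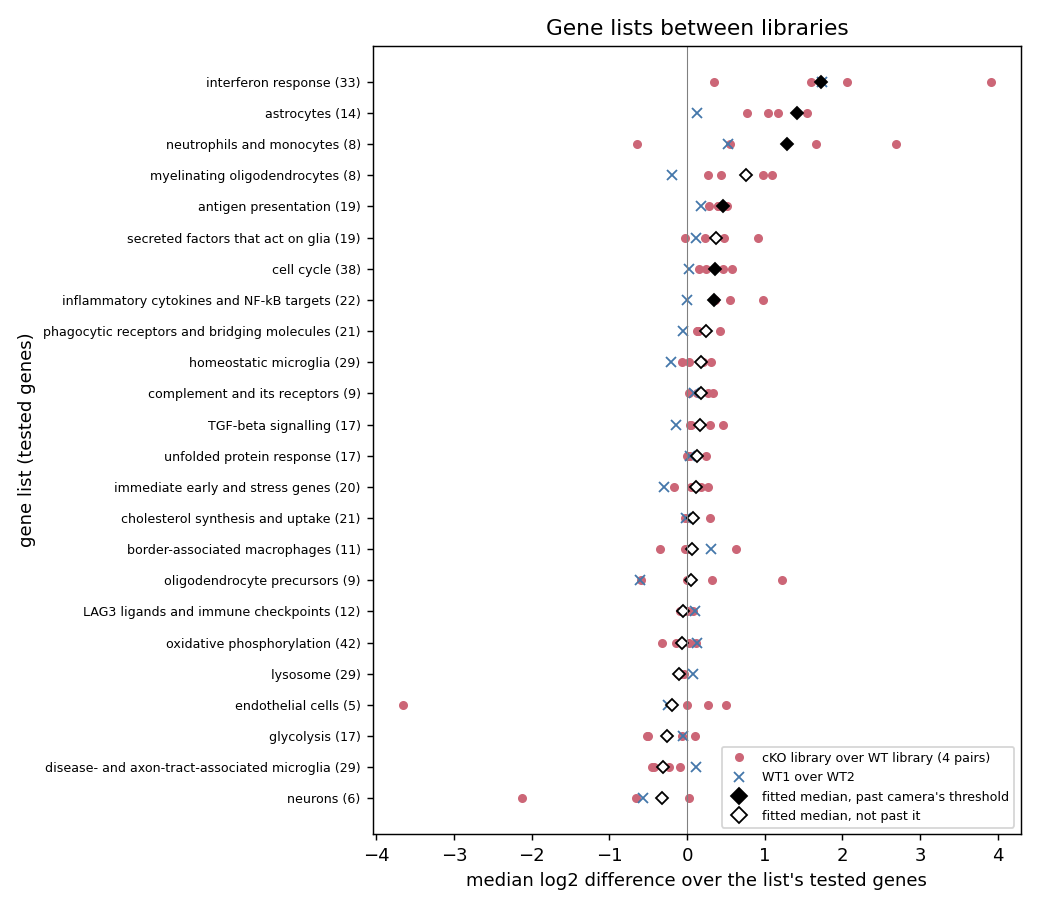
Median log2 difference over each list with at least 5 tested genes, shown for the 4 pairs of a cKO and a WT library (red circles), for WT replicate 1 over WT replicate 2 (blue crosses) and for the edgeR fit (diamonds, filled where camera passed). For interferon genes the cross lies at 1.74, beside the fitted median of 1.73, while for astrocyte markers it lies at 0.12 and the 4 pairs lie between 0.78 and 1.55.

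The last comparison asked how far the 4 single-library comparisons of the authors gave the same genes. Interferon genes called higher in all 4 of the authors' deposited tables were Ifi27l2a, Ifi44, Ifih1 and Oas2, and Lag3 was called lower in all 4. Il1b and Il6 among cytokines and Cxcr2 and Ngp among neutrophil markers were called higher in all 4. Of the astrocyte markers, Fgfr3 and Sox9 were called higher in all 4, and S100b, whose counts were too low for the edgeR test, was called lower in all 4. Of the other lists, the authors' deposited tables called Enpp6, Acta2, Hba-a1, Rpl22l1 and Xist higher, and Hbegf, Cd244, Asns, Mog and Col1a2 lower, in all 4, whereas no homeostatic or disease- and axon-tract-associated gene was called in all 4. Oas2, Il6, Fgfr3, S100b, Hbegf, Cd244, Mog and Col1a2 fall outside the rule for naming genes and were chosen after their values were seen. The authors' deposited tables called 5918, 5900, 7093 and 7735 genes, and 992 were called in the same direction in all 4, 299 higher and 693 lower. A further 383 higher and 369 lower genes were called in 3 tables, and 2191 genes were called in opposite directions in different tables. Each library stands in 2 of the 4 tables, and on the 13086 genes tested here the same call rule gave 793 genes in all 4, against a mean of 728.0 and a range of 665 to 765 in 20 simulated sets of unchanged libraries. The other 2 ways of splitting the libraries into pairs gave 551 and 654 genes, both below the simulated range. The simulation gave all 4 libraries the same dispersion for a gene, whereas the real cKO libraries differed more than the WT libraries. The 793 genes can therefore not be judged against the simulated range. Between the 2 pairs of tables that share no library, 538 and 466 genes were called higher in both where independent lists give 308.5 and 254.7, 893 and 884 were called lower in both where these give 521.6 and 488.2, and 1342 and 1135 were called in opposite directions where these give 848.7 and 716.5.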

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

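The tests on simulated sets and other splits were chosen after the results were seen, and the alternatives here were planned. No gene was called under 8 alternatives (edgeR with 2 other scalings, 2 other filters and the replicate block, and limma with 3 pseudocounts) or with a 2-fold minimum added, where edgeR had 608 genes at an unadjusted p under 0.05. DESeq2 called 52 genes, and leaving out each library gave 0 to 748, the highest without cKO replicate 1. In that fit the lone cKO library is assumed to vary like the WT libraries, so its count is no measure of genes that differ by genotype. Of the 28 lists, 6 passed camera, 0 passed with an estimated correlation and 0 passed with fry, and leaving out each library gave 3 to 6. The replicate number does not mark a shared origin in the labels, and same-numbered libraries did not deviate together (correlation -0.02 across genes); with the replicate block 0 genes and 7 lists passed, adding myelinating oligodendrocytes (adjusted p = 0.0418, median 0.39). With limma on log2(FPKM + 1) 7 lists passed, adding erythroid cells (adjusted p = 0.00705, 2 genes).

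The medians do not depend on the set test, so the calls lost with an estimated correlation and with fry leave them at 1.73 for interferon, 0.35 for inflammatory, 0.46 for antigen presentation, 0.36 for cell cycle, 1.42 for astrocyte and 1.28 for neutrophil and monocyte genes, with adjusted p = 0.681 to 0.762 and, by fry, 0.423 to 0.653. Leaving out each library moved them over 0.93 to 3.43, 0.28 to 0.69, 0.27 to 0.60, 0.19 to 0.52, 0.74 to 1.43 and -0.043 to 2.22. The fitted direction turned when a library was left out for these genes, which did not pass edgeR with all libraries: Cox6c (-0.017 to 0.96), Herpud1 (-0.18 to 1.14), Ptprz1 (-0.28 to 1.38), Mbp (-0.42 to 1.11), Stmn2 (-7.54 to 2.64), Esam (-6.52 to 7.86), Cldn5 (-8.50 to 0.39), Anpep (-2.19 to 0.72), Rgs5 (-9.25 to 0.83), F13a1 (-0.33 to 0.039), Ltf (-6.43 to 7.27), Alas2 (-7.61 to 1.39, and -2.03 with the replicate block), Folr1 (-0.16 to 1.81), Foxj1 (-0.80 to 1.84), mt-Cytb (-0.17 to 0.68), Uty (-12.21 to 0.027), Eif2s3y (-12.96 to 0.14) and Ddx3y (-13.44 to 0.22). Uty, Eif2s3y, Ddx3y, Stmn2, Esam, Cldn5, Rgs5 and Alas2 had no count in cKO replicate 2. Esam also had none in WT replicate 1, and Ltf had none in cKO replicate 1. The cause of these zero counts was not tested. Of the 120 named genes, 12 passed DESeq2. At the authors' adjusted p under 0.001, 737 genes were called in all 4 tables, and a 2-fold minimum left 992, since the tables' own calls already require it.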

Other observations

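The gene lists and their camera and edgeR tests were fixed before the data were examined, and the tests of explanations in the last 3 paragraphs of this part, and the count of list medians that turned, were chosen after the results were seen.

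Among groups of genes with no call, the direction of many differences rested on single libraries. With the range over leaving out each library, the median log2 fold change was 0.24 for phagocytic receptors (0.11 to 0.27), 0.17 for complement genes (0.12 to 0.22), 0.17 for TGF-beta signalling (0.026 to 0.37), -0.10 for lysosomal genes (-0.14 to -0.088) and -0.26 for glycolytic genes (-0.50 to -0.069). The glycolytic median lay at -0.50 and -0.52 in cKO replicate 2 over the WT libraries and at 0.096 and -0.067 in cKO replicate 1. The direction turned for secreted factors that act on glia (0.37, range -0.14 to 0.61), immediate early genes (0.12, -0.042 to 0.32), cholesterol genes (0.08, -0.043 to 0.26), oxidative phosphorylation genes (-0.06, -0.23 to 0.11), LAG3 ligands and immune checkpoints (-0.05, -0.13 to 0.10) and the unfolded protein response (0.12, -0.084 to 0.20). Tgfbr2, a receptor of TGF-beta, had a log2 fold change of -0.48, and Tgfbr1 one of 0.42. Asns, encoding asparagine synthetase, had no count in either cKO library and 8.20 CPM on average in WT, at least 43.3-fold lower against a floor of 3 counts per library, and passed DESeq2 with adjusted p = 0.00292. With Asns at that floor the unfolded protein response list had a mean of -0.28, opposite in sign to its median and to camera. None of these genes passed the edgeR test over all genes.

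Among other cell types without a call, the median log2 fold change was 0.76 for myelinating oligodendrocytes (0.73 to 1.00 over leaving out each library) and 1.77 for erythroid cells (1.25 to 2.55). The direction turned when a library was left out for oligodendrocyte precursors (median 0.05), border-associated macrophages (0.07), lymphocytes (0.09), ependymal and choroid plexus cells (0.60), mural cells and fibroblasts (-0.35), neurons (-0.32) and endothelial cells (-0.19). In all, 13 of the 22 lists without a call turned when some library was left out. The lists of neurons and endothelial cells had means of 0.18 and 0.07, with camera pointing up for both. Cytosolic ribosomal protein genes had a median of -0.07 and a mean of 0.03, and mitochondrially encoded genes a median of -0.04 and a mean of 0.01, with camera pointing up for both. Rps2, of the ribosomal list, had a log2 fold change of -0.90. The list of Y-linked genes and Xist had a median of -0.78, and a mean of 1.25 with Xist at the floor in WT.

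cKO replicate 2 had fewer detected genes than the other libraries, at 12787, and 496 genes were at 0 there with at least 30 counts in each other library, against 39, 25 and 8 such genes in the others. Lower depth is argued against, since after thinning every library to 14645187 counts the lowest of the other 3 still had 14802 genes. A lower share of every other cell type is argued against, since in cKO replicate 2 over cKO replicate 1 the lower quartile lay above 0 for 2 of 7 lists, astrocytes and neutrophils and monocytes, while oligodendrocyte precursors had a median of -1.58 and an upper quartile of -0.87. The median was below 0 for 5 of the 7, among them neurons at -2.04 and endothelial cells at -4.51. Members of both these lists moved apart, with upper quartiles of 1.315 and 0.333. Their summed CPM was not lower in cKO replicate 2, at 79.27 against 45.08 for neurons and 22.54 against 21.56 for endothelial cells. That of oligodendrocyte precursors was lower, at 51.87 against 126.1. Fewer cells of some types stays open, but the medians of neurons and endothelial cells do not show it. A missing Y chromosome as the whole cause is argued against, since 492 of the 496 genes lie on other chromosomes, while a loss of transcripts in preparing this library and other effects of the sex of the animals stay open, untested.

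The higher interferon genes in cKO were weighed against the spread of the libraries. A spread between libraries of one genotype may be as large as the group difference, since WT replicate 1 exceeded WT replicate 2 by a median of 1.738 on the log2 scale. Whether a low WT replicate 2 is the whole cause stays open, since the cKO libraries differ in their median over WT replicate 1, at 0.346 for cKO replicate 1 and 1.592 for cKO replicate 2. The real split gave a median difference of 1.99 and the highest of the other 2 splits 1.62, and 1 of 3 splits reached the real value, too few splits for a share under 0.05. An effect of the genotype stays open, and within it the loss of Lag3 cannot be told from the driver or the lower Cx3cr1. cKO replicate 2, highest for most of these genes, was also the library with the fewest detected genes (12787) and no Ddx3y count. Its markers of neutrophils and monocytes exceeded those of cKO replicate 1 by a median of 1.81 and its astrocyte markers by 0.86. For 5 of the 7 lists of other cell types the median was below 0. The part of these differences in the interferon values was not tested.

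Cx3cr1 had log2 ratios of -1.11 to -0.92 over the 4 pairs of a cKO and a WT library. Fewer microglia in the cKO isolates is argued against, since the lower quartile of the log2 fold changes of the other 28 homeostatic genes was -0.034. A copy of Cx3cr1 taken up by the driver and a change in Cx3cr1 regulation through the loss of Lag3 stay open, untested, since every cKO library carries both.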
